A study of Homo sapiens with 3 samples.

How the data were processed

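RNA from HCT116, an established human colorectal cancer cell line, was sequenced in 3 libraries. Per the labels, 2 libraries came from cells given a small interfering RNA (siRNA) against DUOX2, each with a different sequence, and 1 came from cells given a control siRNA. The libraries with siRNA 1 and siRNA 2 were taken as replicates 1 and 2 of the group with low DUOX2, and the control group had a single library. Nothing in the labels says whether the libraries came from separate cultures. P-values therefore measure only the spread between the 2 siRNA libraries, which holds differences between the siRNA sequences as well as technical variation.

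The deposited table gives raw read counts per gene and, beside them, FPKM values for the same 3 libraries. The authors' FPKM equals the count divided by a gene length and by the sum of the column, since 98.5% of the lengths it implies, over 13617 genes with at least 50 counts, were whole numbers of bases within 0.05. Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and GRCh38 were named, with no role for either build. The gene coordinates in the deposited table are those of GRCh38, and 97.6% of the 58039 genes found in GENCODE 29 had identical coordinates. The counting program, its treatment of strand and its treatment of reads that align to several places are not given in the sources used here. The library protocol in the labels names the TruSeq RNA kit and also speaks of retinas, which does not match the cell line named for the same libraries. Bowtie places reads without splitting them across introns. The treatment of reads across exon junctions and of reads that fit several copies decides how reads are divided between overlapping genes, and between a gene and its processed pseudogenes. Genes named in the text that share at least 10% of their bases with another gene, or have many processed copies, are given as uncertain.

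The table held 58302 genes, of which 31282 had no count in any library. Every row named a gene. The total count was 17589502 in the control library, 19130768 with siRNA 1 and 18832672 with siRNA 2, so that 3 counts, taken as the limit that a count of 0 allows, correspond to between 0.157 and 0.171 CPM, the count scaled to its library total. Poisson intervals on counts are at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

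Differential expression was tested on the deposited counts with edgeR 4.0.16 (R 4.3.3), using TMM scaling, the filterByExpr filter with a minimum count of 10, glmQLFit and glmQLFTest, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter left 17263 genes. The fit had 1 residual degree of freedom and a prior of 4.66 degrees of freedom. The test was also run on simulated libraries, in 5 runs over 16866 genes on average. Each run held 200 changed genes in all, spread over 2-fold, 4-fold and 8-fold changes in either direction. The test recovered 10.0% of 2-fold, 84.8% of 4-fold and 100% of 8-fold changes, with 5.2 false calls per run on average. The simulation gave every gene the median dispersion (0.0508) and changed only genes with a mean count of at least 50. Dispersion varies between genes in the real data, so these rates are not an estimate of recovery there. In the real data 135 genes were beyond 4-fold with both siRNAs, while 10 genes passed the test. Fold changes per siRNA are differences of log2 CPM with a prior count of 2. With 1 library per siRNA and 1 control these have no replicate check, so genes were also counted by a fixed rule of size, at least 2-fold in the same direction with both siRNAs. Both comparisons share the control, so 100 sets of unchanged libraries were simulated from the mean of all libraries with the dispersion between the siRNA libraries.

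The choice of tests, 28 gene lists and the rule for named genes were fixed before the data were examined. The named genes are DUOX2, DUOX1, DUOXA1, DUOXA2 and RPL3, the 12 highest and 12 lowest genes by the smaller of the 2 absolute fold changes (called genes first), the members of each described list with the largest mean fold change, and for each siRNA the 5 highest and 5 lowest genes whose fold change with the other siRNA was within 0.25 of 0. Genes named for their fold change rather than as list members needed at least 50 counts in a library, and pseudogenes and small RNA genes were left out. Other genes named were chosen after their values were seen, and this is said where they appear. For 26 lists the median fold change was ranked among 10000 random lists of the same size matched on mean expression in 20 bins.

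GC content was that of the longest GENCODE 29 transcript of each gene and was known for 99.5% of the genes in the table. The trend of each fold change on GC was estimated by lowess with a fraction of 0.3 (statsmodels) and subtracted, and in a separate edgeR fit the trend of each library entered as an offset. These corrections, the restriction to 10853 protein-coding genes whose exons overlap no other gene on their strand, and the restriction to genes with a mean count of at least 500 were chosen after seeing the data. The siRNA strands were matched to 206694 GENCODE 29 transcripts. For seed matches, the 7-base site paired with guide positions 2 to 8 was looked for in the annotated 3' UTR of the principal coding transcript of genes with a mean count of at least 50, and its effect was ranked among all 7-base sites found in between 1/1.25 and 1.25 times as many genes. Alternatives were DESeq2 1.42.0 (which gave no adjusted p for 5690 genes), limma 3.58.1 on log2(FPKM + 1), other scalings, filters, thresholds and prior counts, and each siRNA library alone. Results for some genes are not reported here.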

Results

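The series set HCT116 colorectal cancer cells labelled as low in DUOX2, an NADPH oxidase that makes hydrogen peroxide, beside control cells. Reads per gene were counted in 3 libraries of 17589502 counts (control), 19130768 counts (siRNA 1) and 18832672 counts (siRNA 2). The 10 most abundant genes took 7.97% of counts in the control, 11.0% with siRNA 1 and 8.22% with siRNA 2. Each siRNA had a single library and so did the control, so values per library carry no replicate error.

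The targeted gene, DUOX2 (ENSG00000140279, chromosome 15, 45092650 to 45114344, GRCh38), had 2 counts in the control library, 2 with siRNA 1 and 0 with siRNA 2. These correspond to 0.114 CPM (95% Poisson interval 0.0138 to 0.411) in the control and 0.105 CPM (0.0127 to 0.378) with siRNA 1. For the 0 counts with siRNA 2 the limit used is 3 counts, or 0.159 CPM, which is not the end of a Poisson interval. All 3 values lie at or under the level of 3 counts, so a difference in DUOX2 was not detectable at this depth, and no fold is given. The target therefore gives no check of the library labels. DUOX1, its closest relative, had 0 counts in the control, 0 with siRNA 1 and 2 with siRNA 2, and the maturation factors DUOXA1 and DUOXA2 had 0 counts in every library. Among the sequences in GENCODE 29, the sense strand of siRNA 1 (GGAGGACAACAUAGUGGUU) matched DUOX2 alone, at 45109537 to 45109555 on chromosome 15, in the coding part of exon 11 of 34. The sense strand of siRNA 2 (CCAUGAUGCGAUCCUUCAU) also matched DUOX2 alone, across the junction of exons 20 and 21 between 45101981 and 45103969, in coding sequence. The control siRNA (UUCUCCGAACGUGUCACGU) matched no transcript without a mismatch. The fewest mismatches to a DUOX1 transcript were 6 of 19 bases for siRNA 1 and 4 for siRNA 2.

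The comparison of the siRNA libraries with the control asked which genes differ when DUOX2 is targeted. Of 17263 genes tested, 10 passed, 3 higher and 7 lower with the siRNAs. MYC, the growth-promoting transcription factor, rose from 281 counts in the control to 2447 with siRNA 1 and 2709 with siRNA 2, which is 8.77-fold and 9.33-fold (log2 fold change 3.19 ± 0.24 SE, edgeR adjusted p = 0.0274). MOAP1, a BAX-binding regulator of apoptosis, fell from 737 counts to 56 and 59 (log2 fold change -3.69 ± 0.24 SE, edgeR adjusted p = 0.0176). TP53INP2, a regulator of autophagy, fell from 829 counts to 32 and 18 (edgeR adjusted p = 0.0274). These were the 3 called genes whose exons overlap no other gene on their strand.

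The other 7 called genes share exons with a neighbour, so the division of reads between the genes is uncertain. PIK3R2, a regulatory subunit of PI3-kinase, had 774 counts in the control, 14 with siRNA 1 and 24 with siRNA 2, while AC007192.1, an overlapping gene, had 0, 439 and 548. RPS10-NUDT3, a read-through of RPS10 into NUDT3, had 6, 572 and 488 counts, while NUDT3 itself, named for its overlap, had 1397, 1890 and 2471. AC120057.2 had 1102 counts in the control and 0 with either siRNA, beside 854, 1324 and 1802 for GABARAP, with which it overlaps. RAB43, a small GTPase, had 1985, 66 and 87 counts. AC020915.5 (628, 1 and 0 counts) and AC092143.1 (615, 1 and 0 counts) completed the set.

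The test was edgeR's quasi-likelihood test with 1 residual degree of freedom, and 4496 genes had an unadjusted p under 0.05. The number called was 539 with DESeq2 (253 higher, 286 lower, all 10 among them), 63 at an adjusted p threshold of 0.10, and 0 without a filter, with at least 1 CPM in every library, with limma on FPKM, in protein-coding genes without exon overlap, at a mean count of at least 500, and with the GC trend removed. Scaling by total count left 9 of the 10, and MYC then had an adjusted p of 0.0752 in edgeR.

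**Figure D1:**
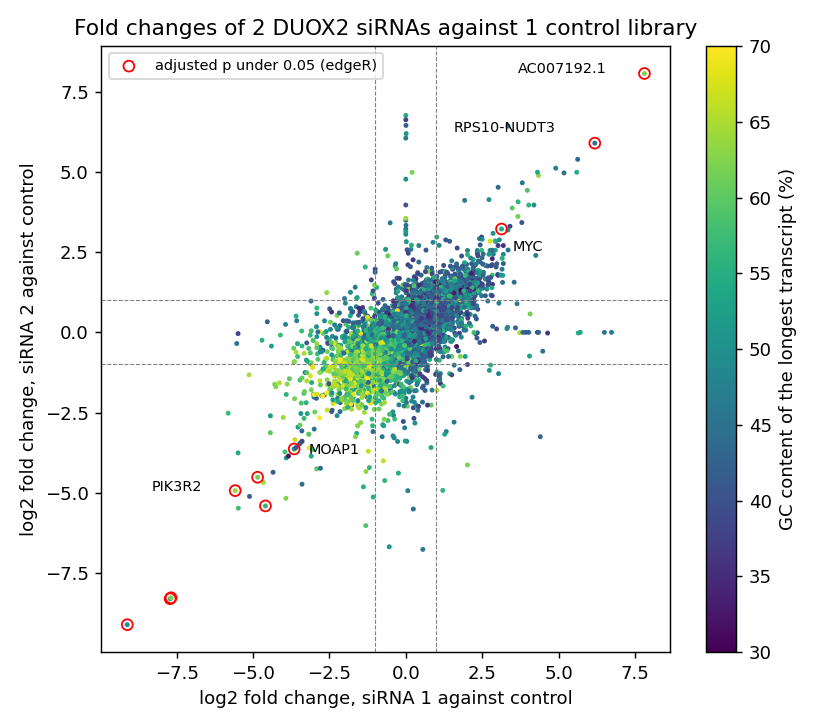
Log2 fold change of each tested gene with siRNA 1 (x axis) and siRNA 2 (y axis) against the control library, coloured by the GC content of its longest transcript in percent. Red circles mark the 10 genes past the edgeR test, and dashed lines mark 2-fold. Genes of high GC content (yellow) lie mostly at the lower left.

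By the rule of size, 1562 genes were at least 2-fold away from the control with both siRNAs, 691 higher and 871 lower, against 346.5 on average in simulated unchanged libraries that share a control (SD 18.8). By direction, the simulated libraries held 222.6 higher and 123.9 lower genes on average. Independent lists of the sizes seen for each siRNA, which leave the shared control out of account, would share 77.1 higher and 167 lower genes. Protein-coding genes without exon overlap made 682 of these, 117 higher and 565 lower. Pseudogenes made 482, of which 433 were higher and 49 lower. Among genes that overlap no other and did not pass the test, chosen after their values were seen, FOSL2, an AP-1 transcription factor, had 3286, 345 and 581 counts in the control, with siRNA 1 and with siRNA 2, and MAP2K4, a stress-activated kinase, had 980, 217 and 219. PTTG1IP had 2312, 10542 and 11474 counts, GABARAPL1, an autophagy protein, had 510, 2614 and 2465, and SOCS6, a suppressor of cytokine signalling, had 41, 449 and 435. HRH1, a histamine receptor, had 5, 95 and 180. With siRNA 1, 3523 genes were beyond 2-fold (1391 higher, 2132 lower), and with siRNA 2, 2311 (957 higher, 1354 lower). Across genes, which are not independent replicates, the fold changes of the siRNAs had a Pearson correlation of 0.737 and a covariance of 0.507, against 0.501 and 0.155 in the simulated libraries. The single control cannot be split, so part of any excess may come from it.

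The fold changes followed the GC content of the genes, taken from the longest transcript of each. In genes under 40% GC the median log2 fold change was 0.58 with siRNA 1 and 0.45 with siRNA 2, and in genes of at least 60% GC it was -1.01 and -0.76. Across genes, Spearman's rho between GC content and fold change was -0.68 with siRNA 1 and -0.64 with siRNA 2 (Pearson -0.60 and -0.53), and -0.31 for the difference between the siRNAs (Pearson -0.21). The 691 higher genes had a median GC content of 44.2% and the 871 lower genes 61.8%, against 48.5% for all tested genes. With the trend removed, 819 genes were beyond 2-fold with both siRNAs (577 higher, 242 lower), and 440 of the higher and 189 of the lower genes remained. MYC (53.9% GC) had log2 fold changes of 3.46 and 3.47 after removal, and MOAP1 (49.8% GC) had -3.61 with either siRNA. TP53INP2 (56.1% GC) had -4.11 and -5.04.

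**Figure D2:**
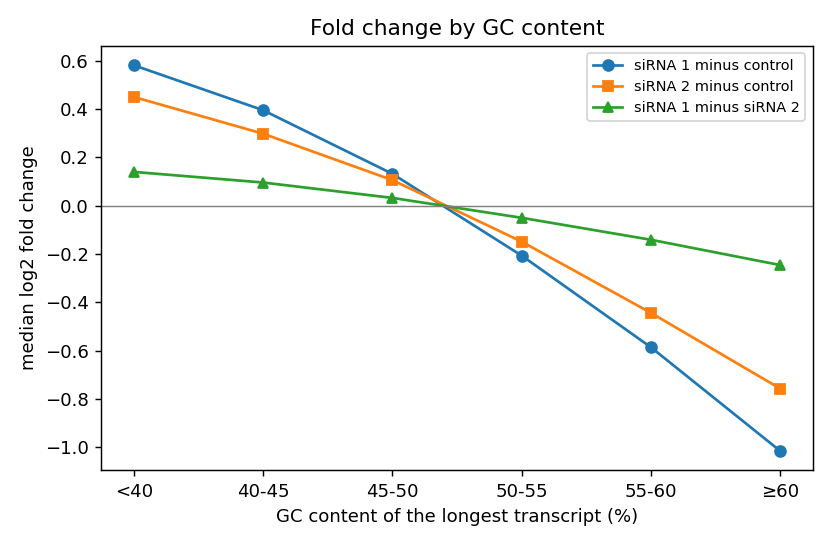
Median log2 fold change of tested genes (y axis) in 6 classes of transcript GC content in percent (x axis), for each siRNA against the control and for siRNA 1 against siRNA 2. Medians run from 0.58 to -1.01 with siRNA 1 and from 0.45 to -0.76 with siRNA 2.

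Among the 28 gene lists, MYC in the list of WNT target genes and PIK3R2 in the list of PI3K, AKT and mTOR components were the members that passed the test over all genes. Removing the GC trend moved many list medians, and these values are given as after removal. Adjustment over a list alone does not account for the number of lists, and its p-values were taken with the GC trend in place. Many of all tested genes had an unadjusted edgeR p under 0.05, so members that pass over a list alone do not single that list out. Among 17 measured WNT target genes, 1 rose and 6 were lower when adjusted over the list alone, among them SP5 (2906, 896 and 1269 counts in the control, with siRNA 1 and with siRNA 2) and NOTUM, a secreted WNT inhibitor (1554, 623 and 751). The median mean log2 fold change of the list was -0.39, and -0.13 with the trend removed (percentile 2.42 of matched random lists). After removal SP5 had -0.47 with siRNA 1 and -0.32 with siRNA 2, and NOTUM had -0.07 and -0.16. Among 24 PI3K, AKT and mTOR components, 4 were lower when adjusted over the list alone. These were PIK3R2, EIF4EBP1 (1364, 633 and 720 counts), RPTOR (1037, 501 and 529) and, chosen after its values were seen, AKT1 (2783, 1556 and 1679). PIK3R2 is uncertain because it overlaps AC007192.1, whose counts changed the other way. The median of this list was -0.05, both before and after removal, and it was 0.01 among genes with at least 1 CPM in every library. It was 0.03 with siRNA 1 and -0.11 with siRNA 2, so its sign differed between the siRNAs. After removal PIK3R2 stood at -4.51 and -4.12, EIF4EBP1 at 0.07 and -0.08, RPTOR at -0.26 and -0.42 and AKT1 at 0.12 and -0.06.

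Of the 6 NADPH oxidase genes measured, 0 passed over all genes, and 1 higher and 3 lower passed when adjusted over the list alone. CYBA, the p22phox subunit, had 1013, 302 and 508 counts, NOXO1 had 31, 8 and 12, NOXA1 had 53, 17 and 25, and RAC1, a small GTPase, had 8036, 15257 and 14030. After removal the log2 fold changes of CYBA moved from -1.72 and -1.03 to -0.85 and -0.37, those of NOXO1 from -1.71 and -1.27 to -0.39 and -0.28, and those of NOXA1 from -1.52 and -1.06 to -0.06 and 0.04. Those of RAC1 moved from 0.94 and 0.77 to 0.66 and 0.54. The median of the list was -0.94 as measured, -0.03 with the trend removed and -0.15 among genes with at least 1 CPM in every library. Of 21 NRF2 target genes, which respond to oxidative stress, 0 passed over all genes and 1 lower when adjusted over the list alone. This was FTH1, the ferritin heavy chain, with 12613, 4762 and 3733 counts. Its 12 pseudogene copies had 15419, 27483 and 12892 counts, and the total over FTH1 and its copies had log2 fold changes of 0.22 and -0.79, against -1.39 and -1.79 for the gene alone, so a lower level of FTH1 with siRNA 1 is uncertain. The list median was -0.30 as measured and -0.02 after removal. Of 17 genes for peroxide and superoxide removal, 0 passed over all genes and 1 lower over the list alone, GPX1, a glutathione peroxidase, with 3131, 190 and 509 counts. Its log2 fold changes were -4.01 and -2.65 as measured and -2.93 and -1.84 after removal, and the list median moved from -0.22 to -0.04.

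In the list of 20 genes of G2 and mitosis, 14 were higher and 3 lower with both siRNAs, and 0 passed over all genes. MKI67, the proliferation marker Ki-67, went the other way from most of the list, at 23853, 9847 and 11388 counts, and was the member past the test when adjusted over the list alone. HMMR had 2811, 5749 and 4418 counts and CDK1, the mitotic kinase, 1895, 3206 and 3407. With the trend removed HMMR moved from 1.05 and 0.61 to 0.45 and 0.14 and CDK1 from 0.78 and 0.81 to 0.19 and 0.34. MKI67 stayed lower, at -1.26 and -1.10 as measured and -1.31 and -1.15 after removal. The median was 0.49 as measured and 0.20 with the trend removed (percentile 99.1). The 20 genes of S phase and replication had a median of -0.0029, which turned to 0.06 after removal, and 0 members passed over all genes or over the list alone. RRM2, whose exons partly overlap AC007240.1 so that its counts are uncertain, had 8855, 18059 and 14621 counts and CDT1 had 1465, 608 and 861. After removal RRM2 had log2 fold changes of 0.83 and 0.51 and CDT1 had -0.12 and 0.05.

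Of 29 interferon-stimulated genes, 0 passed over all genes and 2 lower when adjusted over the list alone, IRF7 (702, 182 and 227 counts) and ISG15 (2142, 605 and 812). After removal IRF7 moved from -1.92 and -1.66 to -0.67 and -0.71 and ISG15 from -1.80 and -1.44 to -0.78 and -0.66. The list median was 0.02 with siRNA 1 and -0.35 with siRNA 2, so its sign differed between the siRNAs, and the mean of both was -0.19 as measured and -0.38 after removal. As measured this mean ranked at percentile 6.73 of matched random lists (41.0 with siRNA 1 and 0.35 with siRNA 2), and after removal it lay below all 10000. The 31 large-subunit ribosomal protein genes had a median of -0.27, and -0.24 after removal, below all random lists in each case. None of them passed over all genes and 5 were lower when adjusted over the list alone, RPL13 (3116, 1281 and 1528 counts) and RPL12 (7980, 3455 and 4215) among them. RPL3 had 8963, 6820 and 6228 counts (edgeR adjusted p = 0.190), with log2 fold changes of -0.38 and -0.56 as measured and 0.07 and -0.22 after removal. The 28 small-subunit genes had a median of -0.13, and -0.28 after removal, with 0 past the test over all genes and 2 lower when adjusted over the list alone, RPS27 (238, 62 and 85 counts) and RPSA (3548, 1621 and 1905). The 17 copies of RPSA had 14472, 17652 and 20081 counts, and the total over RPSA and its copies was higher, at 0.12 and 0.25, against -1.11 and -0.93 for the gene alone. RPS2, which partly overlaps AC005363.1, had 7195, 2607 and 4182 counts without passing. Totals over gene and copies stayed lower for RPS27 (-1.05 and -1.12), RPL12 (-0.45 and -0.28, against -1.19 and -0.96 for the gene alone) and RPS2 (-0.71 and -0.41, against -1.45 and -0.82). Ribosomal protein genes have many processed copies, and their counts are uncertain for that reason.

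Among 20 apoptosis regulators, 0 passed over all genes, and 2 higher and 2 lower when adjusted over the list alone. XIAP, an inhibitor of caspases, had 411, 2290 and 1176 counts and CFLAR, chosen after its values were seen, 417, 916 and 788, while BAK1 had 430, 103 and 181 and BAD 244, 86 and 105. After removal BAK1 had log2 fold changes of -1.33 and -0.74, and BAD moved from -1.46 and -1.24 to -0.25 and -0.32. XIAP moved from 2.49 and 1.47 to 1.98 and 1.07, and CFLAR from 1.15 and 0.88 to 0.84 and 0.64. The list median was 0.06 (-0.04 with siRNA 1 and 0.12 with siRNA 2), turned to -0.05 under total count scaling and was 0.07 after removal. Among 16 FOXO target genes 0 passed over all genes. GABARAPL1 and SESN3 (874, 2455 and 1882 counts) were higher and BCL2L11, the BH3-only protein BIM (816, 290 and 326 counts), lower when adjusted over the list alone, and the median was -0.13 as measured and -0.03 after removal. GABARAPL1 then had log2 fold changes of 2.28 and 2.16 (2.37 and 2.23 as measured). BCL2L11 had -1.69 and -1.53 (-1.47 and -1.36 as measured), and SESN3 had 0.92 and 0.61 (1.51 and 1.07 as measured). Of 24 p53 target genes, 0 passed over all genes and 2 lower over the list alone, GDF15 (350, 101 and 153 counts) and PHLDA3 (1382, 555 and 636), which is uncertain because it overlaps AC096677.2. After removal GDF15 moved from -1.75 and -1.22 to -0.76 and -0.47 and PHLDA3 from -1.29 and -1.16 to -0.54 and -0.58. BBC3, the BH3-only protein PUMA, had 152, 45 and 69 counts without passing, moving from -1.69 and -1.15 to -0.26 and -0.06 after removal, and the list median was -0.17 as measured and -0.01 after removal. In the list of 22 MAPK output genes JUNB had 648, 202 and 219 counts and was the member past the test over the list alone, with none past it over all genes. With the trend removed JUNB moved from -1.65 and -1.59 to -0.53 and -0.75, and the median from -0.29 to -0.01. The list of 22 cholesterol synthesis genes had a median of -0.05 as measured and -0.01 after removal, with 0 past the test over all genes.

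**Figure D3:**
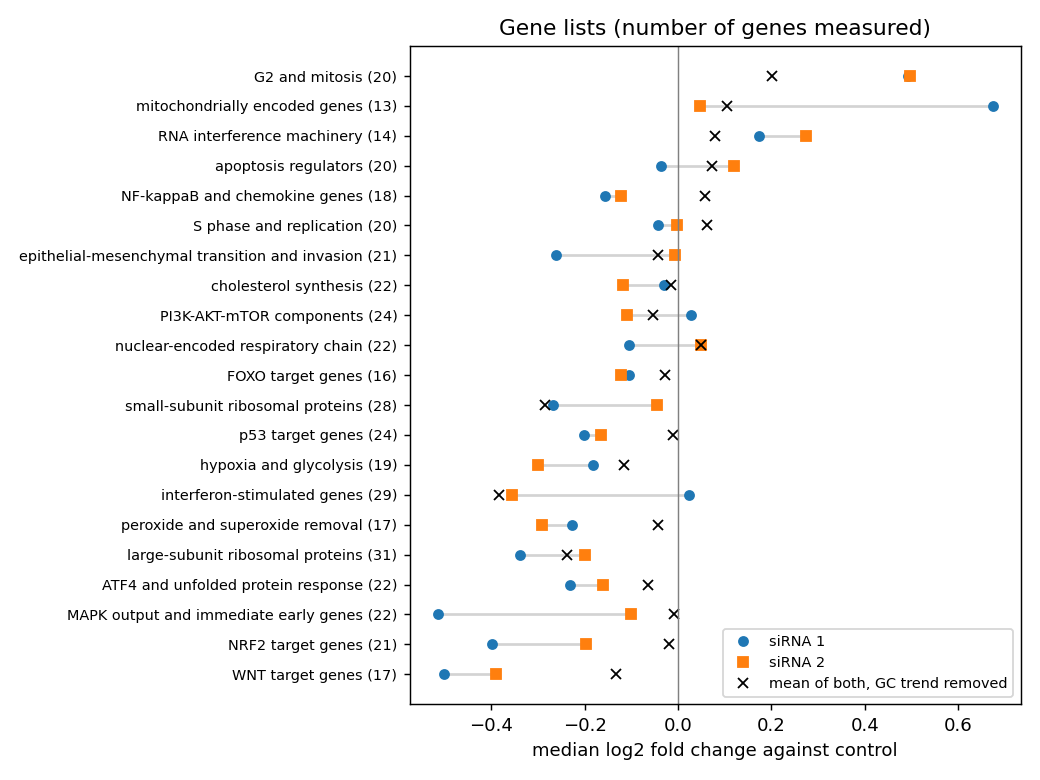
Median log2 fold change against the control (x axis) for each list with at least 10 genes measured (y axis, number of genes in brackets), with siRNA 1, with siRNA 2, and for the mean of both with the GC trend removed. The highest plotted median is 0.67, for mitochondrially encoded genes with siRNA 1, and the lowest is -0.51, for MAPK output genes with siRNA 1.

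Mitochondrially encoded genes took 8.58% of counts in the control, 12.1% with siRNA 1 and 8.83% with siRNA 2. Their median log2 fold change was 0.67 with siRNA 1 and 0.05 with siRNA 2 (0.34 for the mean of both and 0.11 after removal), and none of 13 passed over all genes or over the list alone. MT-ATP6, a subunit of ATP synthase, had 47119 counts in the control, 196823 with siRNA 1 and 58883 with siRNA 2, and shares bases with MT-ATP8.

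Several genes differed from the control with a single siRNA, by the rule that the other siRNA lay within 0.25 of 0. These differences have no replicate and were not tested. KLF13, a Krüppel-like transcription factor, had 1460 counts in the control, 82 with siRNA 1 and 1413 with siRNA 2. CHST14, a sulfotransferase, had 385, 34 and 407, and TNFAIP8L1 had 378, 41 and 366. KCNA2, a potassium channel, had 52, 50 and 5 counts, and HNRNPCL1, which resembles HNRNPC closely, had 59, 61 and 0. Most of the other genes named by this rule share exons with a neighbour, such as RPL17-C18orf32, with 0, 0 and 200 counts, and DNAJC25-GNG10, with 133, 156 and 1.

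Markers of other tissues had low counts. The protocol label speaks of retinas, and the 16 retina markers summed to 199 counts in the control, 127 with siRNA 1 and 145 with siRNA 2, of which RLBP1 took 136, 76 and 104. In the control, with siRNA 1 and with siRNA 2, 11 fibroblast markers summed to 135, 117 and 130 counts, 13 blood cell markers to 176, 70 and 93, and 8 endothelial markers to 40, 19 and 32.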

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

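The test on the division of reads between genes and their copies was chosen after the totals over genes and copies had been seen, and so were the seed tests with trends removed. The tests on GC content and on exon overlap were chosen after the fold changes had been seen.

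In 39 genes the siRNAs lay on opposite sides of the control, at least 2-fold higher with one and at least 2-fold lower with the other. The difference between the siRNAs was not tested, since each has a single library, and 12.2 such genes were found on average in simulated unchanged libraries. Of the 39 genes, 9 are pseudogenes, 18 others overlap a neighbour's exons and 9 are protein-coding without exon overlap. Chosen after their values were seen, MRFAP1 had 661 counts in the control, 4352 with siRNA 1 and 297 with siRNA 2, and CMTR2, an mRNA cap methyltransferase, had 576, 1220 and 224.

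The 1562 genes beyond 2-fold with both siRNAs were weighed against technical explanations. With the trend on GC content removed, 40.3% of them stayed beyond 2-fold, under the 50% that a GC effect as the main source needed, and in protein-coding genes without exon overlap 22.4% of 682 stayed, so a difference in GC response between the control library and the siRNA libraries may account for much of this set. The share beyond 2-fold among protein-coding genes without exon overlap was 69.4% of the share among all tested genes. That lies between the bounds set for and against reads divided between overlapping genes. All tested genes include pseudogenes, of which 24.8% were beyond 2-fold with both siRNAs, so the ratio cannot single out exon overlap. Among protein-coding genes the share was 6.28% without exon overlap and 9.47% with it, and the question stays open. In the 3 splits of the libraries into 2 and 1, edgeR called 10 genes with the control alone, 158 with siRNA 1 alone and 51 with siRNA 2 alone, but 4496, 966 and 300 genes had an unadjusted p under 0.05. The prior degrees of freedom were 4.66 in the first fit and infinite in the others, so the counts of calls come from unlike fits, and 3 splits are too few for a share under 0.05. With the trend as an offset, the called genes without exon overlap had edgeR log2 fold changes of 3.47 (MYC), -3.65 (MOAP1) and -4.61 (TP53INP2), against 3.19 ± 0.24, -3.69 ± 0.24 and -5.05 ± 0.37 (SE) before, and their edgeR adjusted p was 0.146, 0.146 and 0.240, in a fit with 2.99 prior degrees of freedom. An effect of DUOX2 stays open as untested, because the single control library differs from the others in GC response as well as in siRNA. DUOX2 also had only 2 counts in the control library, and DUOXA1 and DUOXA2 had 0, so a loss of DUOX2 could not be seen.

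Pseudogenes were grouped by the symbol of their parent gene, and in 137 of 588 groups the summed copies were at least 2-fold higher with both siRNAs, while in 11 they were at least 2-fold lower. In the 137 groups the copies had a median mean log2 fold change of 1.44 and the parents 0.29. The total over parent and copies had a median of 0.357, above the 0.25 that a pure exchange of reads allows and below the bound against it. These groups were picked for their high copies, which the total contains, so the choice itself favours a high total. Over all 588 groups the medians were 0.650 for the copies, 0.160 for the parents and 0.212 for the total. With the GC trend removed, 71.8% of the 163 copies that were beyond 2-fold in these groups stayed so, which again lies between the bounds set for and against GC content. Neither explanation was excluded, and no biological explanation of the copies was tested. EEF1A1, the group with the most counts in its copies and chosen after its values were seen, was not among the 137 and had 117291, 176892 and 170259 counts in its copies and 35769, 21683 and 29221 in the gene itself in the control, with siRNA 1 and with siRNA 2.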

How the results depend on the processing

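The settings for exon overlap, mean count and GC trend were chosen after seeing the data, and the cause of the changes below was not tested. The 10 calls became 539 with DESeq2, 63 at an adjusted p threshold of 0.10, and 0 with no filter, at least 1 CPM in every library, limma on FPKM, protein-coding genes without exon overlap, a mean count of at least 500, or the GC trend removed. Leaving out a siRNA library left no residual degrees of freedom, so calls have no such test. Genes beyond the fold limit with both siRNAs, siRNA 1 and siRNA 2 numbered 1562, 3523 and 2311. They numbered 4588, 7832 and 6043 at 1.5-fold, 135, 528 and 303 at 4-fold, 2664, 6228 and 4250 with no filter, 900, 2236 and 1304 with at least 1 CPM in every library, and 447, 1326 and 646 on FPKM. They numbered 621, 1670 and 940 in protein-coding genes without exon overlap (scaled anew), 274, 831 and 392 at a mean count of at least 500, and 819, 1868 and 1468 with the GC trend removed. A prior count of 10 gave 983 with both and 1503 with siRNA 2. Without replicate 1 or 2 the count for both became 2311 to 3523, the counts of the remaining siRNA. The lower share of the 1562 was 55.8%. Among the genes beyond the fold limit with both siRNAs in other settings, it was 64.8% with total count scaling, 78.3% without exon overlap and 48.1% at 4-fold. With the GC trend removed, 242 of the 819 were lower. Total count scaling moved the median of all genes to -0.12 with siRNA 1 and -0.07 with siRNA 2. The covariance of 0.507 fell to 0.207 on FPKM, 0.283 at a mean count of at least 500, 0.287 with the GC trend removed, 0.360 with a prior count of 10, 0.367 at 1 CPM and 0.368 in protein-coding genes without exon overlap, and rose to 0.610 with a prior count of 0.5. The DUOX2 mean of the siRNA libraries, 0.0550 CPM with TMM scaling in place of library totals, ranged from 0 to 0.110 without a replicate. Pseudocounts other than 1 on FPKM, and prior counts or FPKM for DUOX2, were not run. The 45 genes of the fold change rule and RPL3 kept their sign under both other scalings, on FPKM and with the GC trend removed, though 24 moved beyond their spread on FPKM, 16 with the GC trend removed and 15 with a prior count of 0.5, and 4 and 2 changed sign without replicates 1 and 2. Of 111 leading list members, 12 changed sign with the GC trend removed, 1 each with total count scaling, on FPKM and without either replicate, and 85 moved beyond their spread with the GC trend removed, 44 on FPKM and 23 with total count scaling. Among 26 list medians, 2 changed sign under total count scaling, 2 with the GC trend removed, 1 of 24 at 1 CPM (where the NADPH oxidases moved from -0.94 to -0.15), and 2 and 4 without replicates 1 and 2. No paired analysis was possible because the control has 1 library. The 2 counts of DUOX2 limit any statement on the knockdown.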

Other observations

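Values with the GC trend removed were computed after seeing the data. Of 22 genes of the ATF4 and unfolded protein response, 15 were lower and 5 higher with both siRNAs, and CHAC1, a glutathione-degrading enzyme, had 132 counts in the control, 56 with siRNA 1 and 68 with siRNA 2. With the GC trend removed the list median moved from -0.27 to -0.06, and the log2 fold changes of CHAC1 moved from -1.19 and -0.97 to -0.22 and -0.24. Of 19 hypoxia and glycolysis genes, 12 were lower with both. CA9, a carbonic anhydrase, had 24, 7 and 12 counts and SLC2A1, the glucose transporter GLUT1, had 20818, 10659 and 12758 counts, with a list median of -0.18 and of -0.12 with the trend removed, which moved CA9 from -1.52 and -0.93 to -0.73 and -0.32. Of 21 genes of epithelial-mesenchymal transition and invasion, SNAI1 had 236, 92 and 115 counts, MMP9, a matrix metalloproteinase, had 52, 14 and 39, and PLAUR, the urokinase receptor, had 851, 404 and 480, with a list median of -0.03 and of -0.04 with the trend removed. The removal moved SNAI1 from -1.32 and -1.06 to -0.67 and -0.56 and MMP9 from -1.74 and -0.43 to -0.79 and 0.29. The lists of NF-kappaB genes and of the nuclear-encoded respiratory chain, with 18 and 22 measured genes, had medians of 0.03 and -0.05. The first turned to -0.07 under total count scaling and the second to 0.05 with the GC trend removed, while the first was then 0.06. These medians are of the mean of both siRNAs. With siRNA 1 and siRNA 2 taken singly they were -0.16 and -0.12 for the first list and -0.10 and 0.05 for the second, so neither sign is firm. None of the genes in these 5 lists passed the edgeR test, over all genes or adjusted over the list alone.

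In the lists of colonocyte, histone, RNA interference and blood cell genes no gene passed over all genes, and 1 or 2 passed when adjusted over the list alone, while in the retina, fibroblast and endothelial lists none passed in either way. CDX2, an intestinal transcription factor in the list of colonocyte and goblet differentiation, had 2001, 893 and 1204 counts. HIST1H2BK, a histone gene, had 986, 450 and 490, and its log2 fold changes moved from -1.11 and -1.04 to -0.24 and -0.39 with the GC trend removed. TSNAX, in the list of RNA interference machinery, had 413, 868 and 1038 and is uncertain because it shares exons with TSNAX-DISC1, while AGO2, the slicing Argonaute, had 1612, 562 and 1604 without passing. Among blood cell markers CD14 had 24, 5 and 5 counts and HBA1 had 58, 12 and 21. The log2 fold changes of TSNAX moved from 1.09 and 1.29 to 0.43 and 0.77 with the trend removed, those of CD14 from -1.88 and -1.92 to -1.25 and -1.44 and those of HBA1 from -2.08 and -1.42 to -0.87 and -0.50. With the GC trend removed the medians of these 4 lists moved from -0.42 to -0.31, from 0.20 to 0.08, from 0.24 to 0.08 and from -0.99 to -0.75 in that order, and that of the retina markers from -0.65 to -0.05.

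A further question was whether the siRNAs acted on genes through seed matches, and for this the 7-base sites for guide positions 2 to 8 were compared over 11257 genes. Bounds were set before the data were examined, at a rank in the outer 1% of sites for such an effect and beyond 5% against it. As measured, genes with the siRNA 2 site (TCCTTCA, 1687 genes) had a median siRNA 2 minus siRNA 1 difference 0.13 below genes without it on the log2 scale, and 0.166% of 3604 sites lay as low, while for siRNA 1 (TAGTGGT, 879 genes) the rank was 27.1% of 3180 sites, which argues against a seed effect by the bound set. The control site (TGTCACG, 323 genes) ranked at 35.7% from the highest, which also lies beyond the bound set against one. The differences followed GC content, with a Spearman's rho across genes of -0.39 for siRNA 1 minus siRNA 2. For the mean of both siRNAs against the control, used for the control site, rho was -0.78. With so strong a trend, the rank of the control site as measured cannot exclude a seed effect. A test with trends on GC and 3' UTR length removed was then added after these ranks had been seen. In it 0.0629% of sites lay as low as that of siRNA 1, that of siRNA 2 was the lowest of all (0.0277%), and the control site ranked at 2.52% from the highest, between the bounds. A seed effect of siRNA 2 met the bound in both tests and is a candidate explanation for part of its difference from siRNA 1. For siRNA 1 the tests disagree, the favourable one was chosen after the other had failed, and the question stays open. For the control siRNA the added test fell between the bounds, and the question stays open as well. With trends removed, 25.6% of the 587 genes at least 1.5-fold lower with siRNA 2 held its site, against 14.4% of the other genes. The corresponding shares were 11.4% of 594 genes against 7.61% for the siRNA 1 site, and 4.23% of 544 genes against 2.80% for the control site. A higher share was thus not particular to siRNA 2.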
